A study of Oryza sativa Japonica Group with 12 samples.

How the data were processed

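Roots of rice seedlings of the cultivar Nipponbare were profiled by 3′ mRNA sequencing, in which a read marks the 3′ end of a transcript. Per the labels' protocols, plants were transplanted 5 days after germination and grown at 28 °C with 12 h of light. Leaves were sprayed 13 days after transplanting with 300 µM piperonylic acid or with a mock solution, both with 0.1% Tween 20. Piperonylic acid is an inhibitor of cinnamate 4-hydroxylase, an early enzyme of the phenylpropanoid pathway. Roots of 4 plants were pooled per sample, and libraries were made from 2 µg of RNA. Groups and replicate numbers came from the sample titles, which gave 3 samples for each treatment at 6 h and 24 h. The numbers in the source names of 3 piperonylic acid samples differed from their titles. An inoculation of these roots and an earlier spray are not established by the labels used here.

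The submitters' processing notes name FastQC 0.11.8, Trimmomatic 0.38, STAR 2.6.1d and DESeq2; the counting tool and genome build are not given in the sources used here. The authors deposited 1 table of a normalised signal per gene, which the values show to be read counts divided by a size factor per sample. In each column at least 99.985% of the values above 0 were whole multiples of the value of 1 read within 0.01, and 100% were so up to 1000 reads, so whole reads could be recovered. The recovered totals ran from 6302056 to 20301774 reads per sample, and they limit what can be seen of genes with few reads. The size factors equalled median-of-ratios factors computed within each time to within 8.2e-06%, and differed by up to 11.1% from those computed over all 12 samples. The times had therefore been scaled separately, which left a median log2 difference of 0.30 between mock roots at 24 h and 6 h. This constant largely cancels in each treatment effect and in their difference, and it enters the comparison of the times. For genes with few counts it does not cancel fully, because 2 is added to each value before the log.

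The table held 35833 rows, of which 4356 were 0 in every sample. Genes with a mean of at least 10 normalised counts over the 12 samples were tested, 19207 in all. Values were taken as log2(normalised count + 2), so fold changes of low genes are understated. limma 3.58.1 in R 4.3.3 fitted 4 group means to all 12 samples, with a mean-variance trend and robust moderation, and p was adjusted by the Benjamini-Hochberg method at 0.05. edgeR 4.0.16 and DESeq2 1.42.0 were run on the recovered reads as alternatives. The samples were pools of separate plants as far as the labels say, with nothing stated on separate cultures or days, so p measures the spread between these samples.

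Gene lists were tested with camera at a preset correlation of 0.01, with an estimated correlation, and with fry. Lists needed at least 5 tested genes. Before the data were examined, 58 lists were fixed, of which 20 held identifiers and the rest relied on descriptions that no file gave; 11 could be tested. Another 18 were added after the table had been opened and before groups were compared, of which 17 could be tested. The planned and the added lists were adjusted as separate families, a split made after the pooled result had been seen and in keeping with the planned family; results also give the pooled adjustment where it changed a call. The list test of the difference between the times was also added later. The deposited table does not pair its identifiers with names, and the reference table matched 1 of the 35833. List memberships were therefore written from recalled published loci and could not be checked against a file, so a list's name is the intended content of its identifiers, and 1 of the 5 identifiers in the DREB list is doubtful. The rule for named genes asked for product names and so named no gene. In its place 4 identifiers are printed, the largest rise and the largest fall at each time among called genes with separated replicates, a rule set after results had been seen.

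Same-numbered samples were checked for pairing by correlating their deviations from the group means. At 6 h the correlations were 0.305, 0.288 and 0.126, against at most 0.0341 between different numbers, so the numbers of the titles were taken to pair the samples there. The deviations within a group cancel out, so low correlations between different numbers partly follow from higher ones between the same numbers. The pairing is therefore tentative, and the main fit did not use it. This pairing and the fits with a replicate block rest on those numbers, and the block was also fitted with the numbers of the source names. At 24 h they were -0.187, 0.0505 and 0.0212, and the samples were treated as unpaired. Replicates of a group differed by more than sampling noise, with a chi-square per degree of freedom of 5.17 to 27.8, so no library was counted as a repeat of another.

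The procedure was tested on simulated counts for the 19207 genes, with 200 changed genes per effect. For the 6 h comparison it recovered 22.4% of genes changed 1.5-fold, 58.2% of those changed 2-fold and 90.9% of those changed 4-fold, and 5.79% of its calls were wrong. For the 24 h comparison the shares were 5.97%, 61.2% and 89.4%, with 7.96% wrong calls. In the list test, 10 of 10 raised lists and 0 of 10 unchanged lists were called. The simulated genes were independent, which real genes are not. Alternatives covered the pseudocount, the filter, the scaling, the samples in the fit, a replicate block, sample weights, the count-based tests and leaving out each sample in turn. Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9 were used for tables and figures.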

Results

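The data comprised 12 root libraries, 3 for each of mock and piperonylic acid at 6 h and at 24 h after a foliar spray. Recovered reads were between 6302056 and 10254382 in 11 libraries and 20301774 in replicate 1 of the 24 h mock group. The 10 most abundant genes took between 10.02% and 12.15% of the reads of a library. Computed on the values as deposited, the first principal component held 48.0% of the variance and separated the times. The median log2 difference of 0.30 that the separate scaling left between the times enters this component. On it the 6 h mock libraries lay at -50.0, -50.5 and -57.9, and the 6 h piperonylic acid libraries at -21.8, -25.9 and -42.1. Replicate 2 of the 24 h mock group stood apart on the third component, at 51.6 against values from -21.5 to 8.60 in the other libraries.

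**Figure D1:**
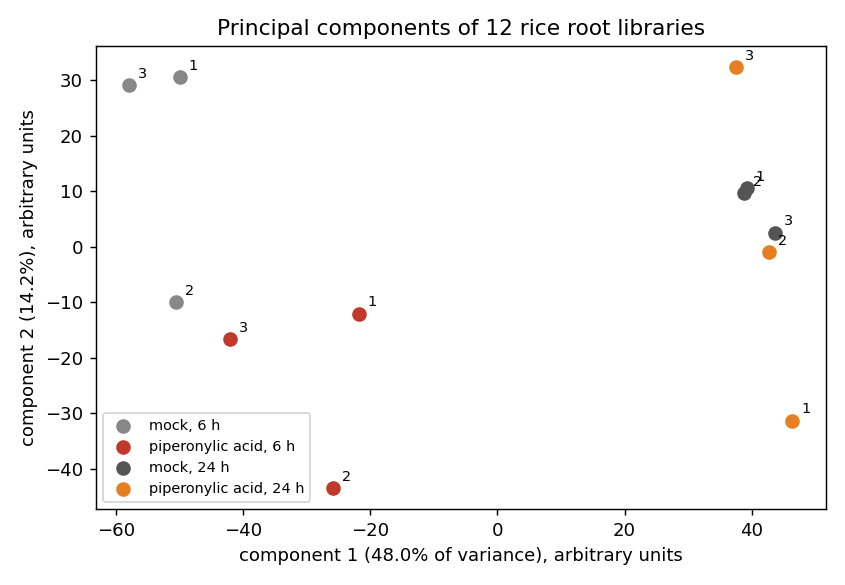
Principal components 1 and 2 of log2 values of 19207 genes, 1 point per library with its replicate number, in arbitrary units. The 6 h piperonylic acid libraries lie at -21.8, -25.9 and -42.1 on component 1, nearer to the 24 h libraries than the 6 h mock libraries do.

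The first comparison asked which root transcripts differed 6 h after the spray. List names give the intended content of identifiers that could not be checked against a file. Genes listed for diterpenoid phytoalexins, the antimicrobial compounds of rice, rose as a group, with 16 of 17 members higher in treated roots and a median log2 fold change of 0.91. Genes listed for PR1, PR5 and PR10 pathogenesis-related proteins rose as a group as well, with 5 of 5 higher and a median of 1.32. Genes listed for the jasmonate response, which include JAZ repressors, fell as a group, with 7 of 8 lower and a median of -1.08. WRKY transcription factors fell, with 5 of 6 lower and a median of -0.54. In camera with the preset correlation the adjusted p was 0.00257 for the first 3 lists and 0.00700 for the WRKY factors, and with an estimated correlation adjusted p = 0.614 for each of them. No member of these 4 lists passed over all genes tested by limma or edgeR, while 4 diterpenoid phytoalexin, 1 PR, 3 jasmonate response and 3 WRKY genes had an unadjusted limma p under 0.05. Adjusted over the list alone, 1 diterpenoid phytoalexin gene was higher, at 0.38, 2 WRKY factors were lower, at -1.88 and -1.83, and 0 PR and 0 jasmonate response genes passed. With a replicate block within each time by the source-name numbers the jasmonate response and WRKY calls were lost, each at an adjusted p of 0.0559 and at medians of -0.82 and -0.34. Without mock replicate 2 the WRKY call was lost, at 0.0613, and without treated replicate 2 the diterpenoid phytoalexin median was 0.48.

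Library scores, the mean over a list's genes of the log2 value minus the mean of that time, showed the spread behind these groups. The diterpenoid phytoalexin score was 0.46 ± 0.65 (SD, n = 3) in treated and -0.46 ± 0.23 (SD, n = 3) in mock roots, and replicate 3 of the treated group, at -0.25, lay below mock replicate 3, at -0.19. The PR score was 0.65 ± 0.48 (SD, n = 3) against -0.65 ± 0.53 (SD, n = 3). The jasmonate response score was -0.57 ± 0.60 (SD, n = 3) against 0.57 ± 0.39 (SD, n = 3). Within the pairs given by the title numbers, the jasmonate response score was lower in treated roots in 3 of 3, with a difference of -1.14 ± 0.29 (SD, n = 3 pairs). The WRKY score was lower in 3 of 3, with -0.77 ± 0.12 (SD, n = 3 pairs). The PR score was higher in 3 of 3, with 1.30 ± 1.01 (SD, n = 3 pairs), and the diterpenoid phytoalexin score in 2 of 3, with 0.93 ± 0.87 (SD, n = 3 pairs). Genes listed as leaf and photosynthesis markers, included to detect shoot tissue, fell too, with 6 of 7 lower, a median of -0.66 and an adjusted p of 0.0353 by camera, against adjusted p = 0.614 with an estimated correlation. Their score was highest in replicate 2 of the mock group, at 1.26, and the difference within pairs was -0.68 ± 1.09 (SD, n = 3 pairs), negative in 2 of 3. The call was lost without that library, at an adjusted p of 0.567, and without treated replicates 2 and 3 in turn, at 0.0671 and 0.157, as well as with the source-name block, at 0.0559, and the median was -1.05 without mock replicate 1.

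Of the lists added later, those for DREB transcription factors, which act in cold and drought responses, for WRKY factors in a longer version that holds the shorter list and for dividing cells fell at 6 h. All 5 listed DREB genes were lower, with a median of -2.16, and 3 passed over the list alone, at -2.74 to -2.16. The longer WRKY list had 13 of 17 lower and a median of -0.30, with 5 passing over the list alone. The dividing-cell list had 6 of 7 lower and a median of -0.37, with 3 passing over the list alone. Their adjusted p by camera was 0.000656, 0.000656 and 0.00609, and with an estimated correlation adjusted p = 0.541 for each. Without mock replicate 1 the dividing-cell call was lost, at an adjusted p of 0.0882, and the median of the longer WRKY list was -0.47, against -0.83 with a minimum mean of 50. The genes of phenylpropanoid entry, the enzymes around the step that piperonylic acid inhibits, did not pass at 6 h: 0 of 13 changed by limma or edgeR, with 6 positive, 7 negative and 2 at an unadjusted p under 0.05. The lists for the monolignol branch, jasmonate synthesis, nitrate and ammonium, iron deficiency and the circadian clock did not pass either, nor did the 14 other added lists. Among the latter the longer phosphate list, with 9 of 10 positive and a median of 0.20, had an adjusted p of 0.0519 within the added lists. It passed at 0.0428 when planned and added lists were adjusted together, and had adjusted p = 0.541 with an estimated correlation. The pooled call was lost without mock replicate 1 and treated replicates 2 and 3 in turn, at 0.366, 0.0771 and 0.108.

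Over all genes, limma called 319 of 19207 changed at 6 h, 146 higher and 173 lower, edgeR called 308, and DESeq2 called 679, 223 higher and 456 lower. Of these 319, 94 changed over 2-fold, 22 upward and 72 downward. In all 319 the 3 treated libraries lay on the same side of the 3 mock libraries, which their selection by the same difference makes likely. Of all genes tested 19.6% did so, where chance gives 10% if libraries are exchangeable. The largest rise was in Os02g0541500, from 1.24 ± 1.41 to 9.39 ± 1.54 normalised counts (SD, n = 3 each), a log2 fold change of 1.90 ± 0.38 (SE) with a limma adjusted p of 0.0264. The largest fall was in Os09g0535500, from 39.1 ± 13.4 to 5.07 ± 4.74 normalised counts (SD, n = 3 each), a log2 fold change of -2.72 ± 0.57 (SE) with a limma adjusted p of 0.0307. Both are expressed at low levels, and the call was lost for both without mock replicates 1 and 3 and treated replicates 1 and 2 in turn, and for the second also without mock replicate 2. With a pseudocount of 0.5 the second call was lost, at an adjusted p of 0.106, and the first log2 fold change was 2.88, against 0.92 with a pseudocount of 8; with only the 6 h libraries the first call was lost, at 0.102. With a replicate block within each time the count was 802 by the numbers in the titles and 65 by those in the source names, which give 3 treated samples another number, and by the latter both calls were lost, at 0.125 and 0.192. It was 4 without mock replicate 3, 11 without treated replicate 1, 17 without treated replicate 2, 741 without treated replicate 3 and 190 without mock replicate 2, and through the shared estimate of spread 174, 207 and 139 without mock replicates 1 and 3 and treated replicate 2 of 24 h.

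**Figure D2:**
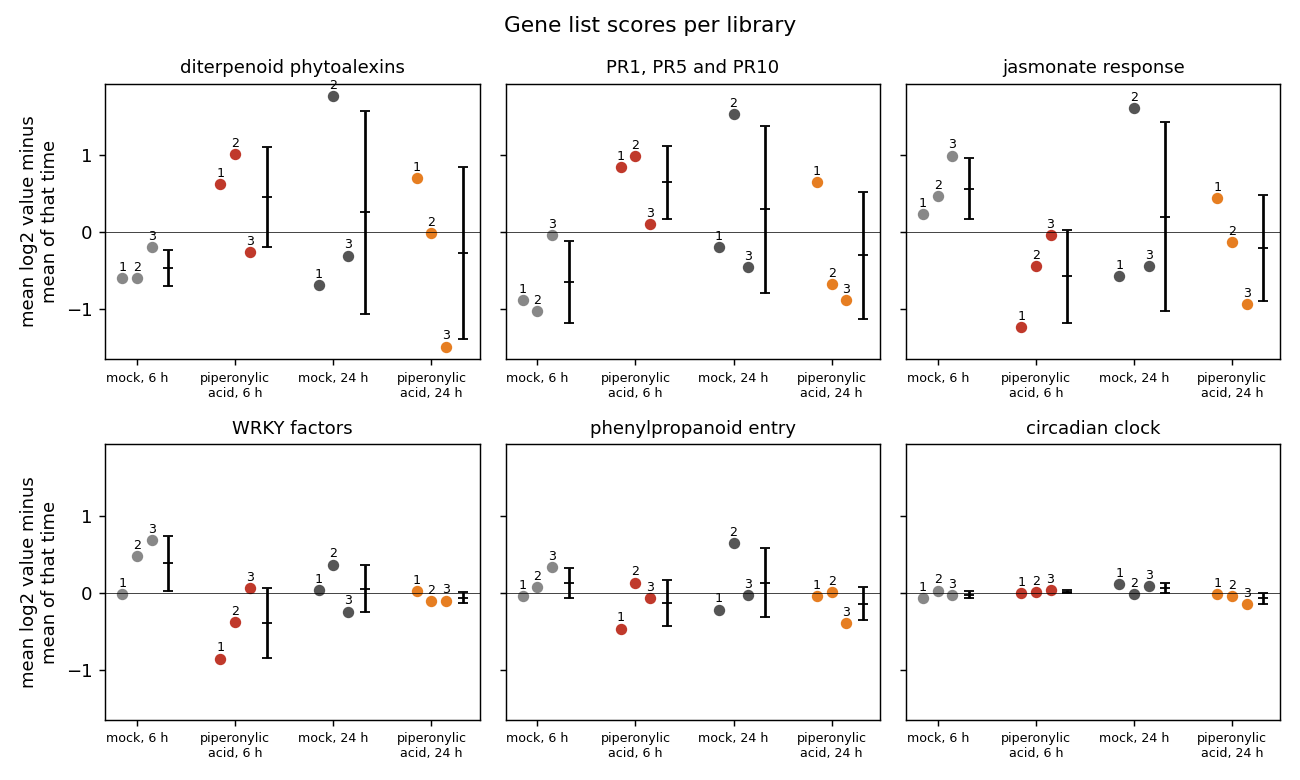
Scores of 6 gene lists in the 12 libraries, as the mean log2 value minus the mean of the 6 libraries of that time; points are libraries with their replicate numbers, bars the mean and SD of 3. The diterpenoid phytoalexin score of the 24 h mock replicate 2 is 1.77, while the other mock libraries of that time lie at -0.68 and -0.30.

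The same question was asked of roots at 24 h. Genes of phenylpropanoid entry fell as a group, with 11 of 13 lower and a median log2 fold change of -0.18, and genes of the monolignol branch, which leads to lignin, fell with 7 of 7 lower and a median of -0.12. Genes listed for diterpenoid phytoalexins fell as well, with 16 of 17 lower and a median of -0.46. Their camera adjusted p was 0.0358, 0.0260 and 0.0358, and with an estimated correlation adjusted p = 0.645 for each. Of 10 splits of the 24 h libraries, 7 gave as many planned lists by camera, the real split included. The number of list calls therefore does not set treated from mock roots apart. No member of the 3 lists passed over all genes tested by limma or edgeR, and 1 monolignol and 0 other members had an unadjusted limma p under 0.05. Adjusted over the list alone, 1 monolignol gene was lower, at -0.59. Replicate 2 of the mock group carried high values of these lists, with a diterpenoid phytoalexin score of 1.77, a jasmonate response score of 1.62, a PR score of 1.54 and a phenylpropanoid entry score of 0.65. Without it, or without treated replicate 3, none of the 3 lists passed: the adjusted p was 0.499 and 0.404 for phenylpropanoid entry, 0.0670 and 0.0946 for monolignol and 0.499 and 0.994 for diterpenoid phytoalexin genes. The median of the last list turned to 0.29 and 0.06, and that of phenylpropanoid entry was -0.08 and -0.10. Without mock replicate 1 the medians of phenylpropanoid entry, monolignol and diterpenoid phytoalexin genes were -0.29, -0.19 and -1.001, and that of the last was -0.79 without mock replicate 3 and -0.99 without treated replicate 1. With sample quality weights none of the 3 passed, and the medians of phenylpropanoid entry and diterpenoid phytoalexin genes were -0.11 and 0.02, and with no filter or a minimum mean of 50 phenylpropanoid entry and diterpenoid phytoalexin genes did not, at adjusted p from 0.0593 to 0.113, with the former at a median of -0.12 in both. With the source-name block the diterpenoid phytoalexin median was -0.83. Jasmonate synthesis, jasmonate response and PR genes did not pass, at medians of -0.26, -0.42 and -0.57, nor did WRKY factors, nitrate and ammonium, iron deficiency, leaf markers or the circadian clock.

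Among the added lists at 24 h, aquaporins, the water channels of membranes, were higher, with 12 of 13 positive and a median of 0.20, and heat shock proteins were higher, with 7 of 8 positive and a median of 0.44. The camera adjusted p was 0.000109 and 0.000915, and with an estimated correlation adjusted p = 0.783 and 0.249. Adjusted over the list alone, 0 aquaporins and 3 heat shock genes passed, the latter at 0.34 to 0.91. Without mock replicate 2 the aquaporin median was 0.07 and the call was lost, at an adjusted p of 0.106, and without treated replicate 3 the heat shock call was lost, at 0.0654. With the source-name block the heat shock median was 0.28. The 15 other added lists did not pass. Among them chitinases and beta-1,3-glucanases, with 10 of 12 negative and a median of -0.61, had an adjusted p of 0.0574 within the added lists. They passed at 0.0473 when planned and added lists were adjusted together, and had adjusted p = 0.783 with an estimated correlation. The pooled call was lost without mock replicate 2, at 0.987 and a median of -0.02. It was also lost without treated replicates 2 and 3 in turn, at 0.113 and 0.452, and without mock replicate 1 and treated replicate 3 of 6 h in turn, at 0.0504 and 0.0567. The median was -0.96 without mock replicate 3.

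Over all genes, limma called 22 at 24 h, 11 higher and 11 lower, and edgeR called 26. DESeq2 called 53, 30 higher and 23 lower. All 22 had treated libraries on the same side of the mock libraries, which their selection by the same difference makes likely. Of all genes tested 11.8% did so, where chance gives 10% if libraries are exchangeable. The largest rise was in Os07g0631200, from 21.1 ± 8.52 to 88.9 ± 8.51 normalised counts (SD, n = 3 each), a log2 fold change of 2.05 ± 0.25 (SE) with a limma adjusted p of 0.00311. The largest fall was in Os01g0915000, from 285 ± 76.4 to 125 ± 8.38 normalised counts (SD, n = 3 each), a log2 fold change of -1.14 ± 0.17 (SE) with a limma adjusted p of 0.0166. The count was 3 without mock replicate 2, 3 without mock replicate 3, 5 without treated replicate 1, 5 without treated replicate 2 and 7 without treated replicate 3. The call of Os01g0915000 was lost without each of these 5 libraries in turn, at log2 fold changes from -1.19 to -0.95, and that of Os07g0631200 was not lost in any of the 12 refits. With a replicate block within each time by the source-name numbers the count was 0 by limma, with 1330 genes at an unadjusted p under 0.05, and both calls were lost, at 0.0542 for Os07g0631200 and 0.0942 for Os01g0915000.

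Whether the response differed between the times was tested directly. Genes listed for diterpenoid phytoalexins had effects lower at 24 h than at 6 h, with 16 of 17 differences negative and a median log2 difference of -1.26, and PR genes likewise, with 5 of 5 negative and a median of -1.84. WRKY factors had effects higher at 24 h, with 6 of 6 positive and a median of 0.48, and monolignol genes had lower ones, with 7 of 7 negative and a median of -0.19. By camera the adjusted p was 0.000204, 0.000553, 0.0216 and 0.00899, and with an estimated correlation adjusted p = 0.547 for each. The first 2 passed in each of 12 refits without 1 library, though without mock replicate 2 of 24 h the medians were -0.57 and -1.06, and without mock replicate 1 of 24 h the first was -1.99. These refits keep the preset correlation, and the list test of the difference was not set against splits of the libraries. The WRKY call was lost without mock replicate 2 or 3 or treated replicate 1 of 6 h and without mock replicate 3 or treated replicate 1 of 24 h, at adjusted p from 0.0578 to 0.108. The monolignol call was lost without treated replicate 2 of 6 h, at 0.0783, and its median was -0.31 without mock replicate 2 and -0.29 without treated replicate 1 of that time.

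Of the 17 added lists, 7 passed the same test, and with an estimated correlation adjusted p = 0.365 for heat shock proteins, 0.468 for DREB factors, dividing cells and type-A response regulators and 0.497 for the others. Heat shock proteins had effects higher at 24 h, with 7 of 8 differences positive and a median of 0.36, and DREB factors likewise, with 4 of 5 positive and a median of 2.21. Their camera adjusted p was 0.00633 and 0.0137, and both passed in each of 12 refits, though the heat shock median was 0.67, 0.61 and 0.69 without mock replicates 1 and 2 and treated replicate 1 of 6 h. Dividing-cell genes had 7 of 7 positive, a median of 0.40 and an adjusted p of 0.0137, which was 0.0663 without mock replicate 1 of 6 h, and the median was 0.26 without mock replicate 2 of 24 h. Type-A response regulators, which act in cytokinin signalling, had 6 of 6 positive, a median of 0.35 and an adjusted p of 0.0212, which was 0.117 without mock replicate 1 of 6 h and 0.148, at a median of 0.22, without mock replicate 2 of 24 h. The longer WRKY list had 12 of 17 positive, a median of 0.44 and an adjusted p of 0.0212, and was lost without the same 5 libraries as the shorter list, at medians from 0.20 to 0.39. The longer phosphate list had 7 of 10 negative, a median of -0.21 and an adjusted p of 0.0403. It was lost without mock replicate 1 or treated replicate 3 of 6 h and without mock replicates 1 and 3 and treated replicates 2 and 3 of 24 h in turn, and its median was -0.10 without mock replicate 3 and -0.40 without mock replicate 2 of 24 h. Chitinases and beta-1,3-glucanases had 9 of 12 negative, a median of -0.57 and an adjusted p of 0.0450, and were lost without mock replicate 2 or treated replicates 1 and 3 of 6 h and without mock replicate 2 or treated replicates 2 and 3 of 24 h in turn, with a median of -0.29 without mock replicate 2 of 24 h.

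Over all genes the treatment effect differed between 6 h and 24 h for 106 by limma, with 40 more positive and 66 more negative at 24 h, and for 89 by edgeR, with 32 and 57. DESeq2 called 342, of which 101 were among the 106, and its balance of directions was the opposite, with 189 more positive and 153 more negative. Of 6 genes called at both times, all 6 were higher in treated roots at 6 h and lower at 24 h. Independent lists of these sizes would share 0.0836 genes in that pattern, but these lists are not independent, so chance is not measured. Both times share 1 estimate of each gene's spread, and genes can move together. The 6 cannot all hold in every refit, since 4 genes passed at 6 h without mock replicate 3 of 6 h. At 24 h, 3 passed without mock replicate 2 or 3, 5 without treated replicate 1 or 2, and 0 with the source-name block. Across genes, which are not independent replicates, the log2 fold changes of the times correlated with r = 0.031. Of the 319 genes called at 6 h, 128 (40.1%) had the same sign at 24 h, and of the 22 called at 24 h, 5 had the same sign at 6 h. The 6 genes called at both times are among the called genes of each count. With a replicate block within each time the count of 106 was 376 by the numbers in the titles and 25 by those in the source names. It was 56, 44, 56, 42 and 471 without mock replicates 2 and 3 and treated replicates 1, 2 and 3 of 6 h in turn, and 56, 60, 63, 38 and 53 without mock replicates 1 and 3 and treated replicates 1, 2 and 3 of 24 h.

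The mean effect over both times passed for 10 genes by limma, 6 higher and 4 lower, for 3 by edgeR, for 153 by DESeq2, 75 higher and 78 lower, and for 2116 at an unadjusted limma p under 0.05. With a replicate block within each time the count was 202 by the numbers in the titles and 0 by those in the source names, with 1883 genes at an unadjusted limma p under 0.05 in the latter. It was 0 without mock replicate 3, treated replicate 1 and treated replicate 2 of 6 h and without treated replicates 1 and 2 of 24 h in turn, with 1603 to 1851 genes at an unadjusted p under 0.05. It was 246 without treated replicate 3 of 6 h and 2, 5 and 18 without mock replicates 2 and 3 and treated replicate 3 of 24 h.

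**Figure D3:**
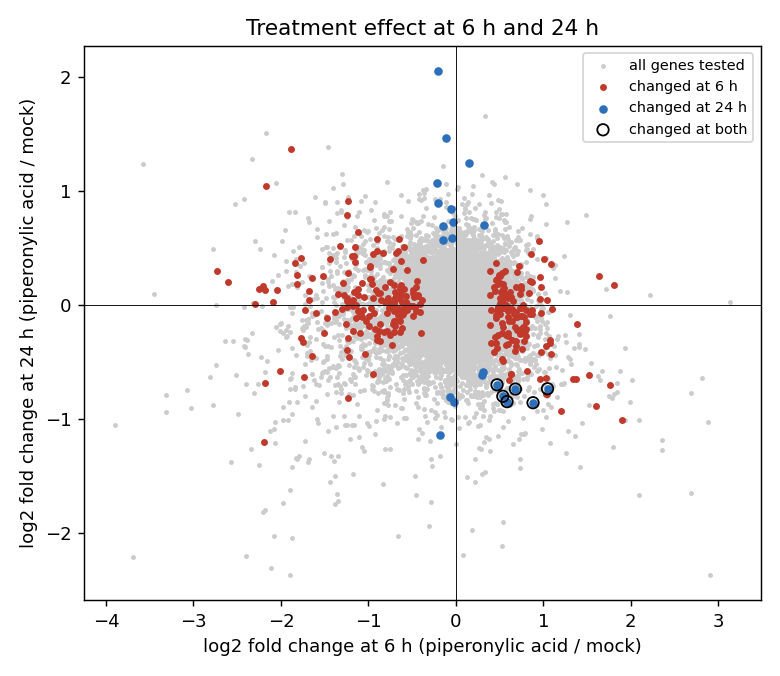
Log2 fold change of piperonylic acid over mock at 6 h (horizontal) and 24 h (vertical) for 19207 genes; red points passed at 6 h, blue at 24 h and circled points at both. The 6 circled genes are positive at 6 h and negative at 24 h.

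The time course of mock roots gave the background for these effects. Values below are relative to the median difference of 0.30 that the separate scaling left between the times. Of 8 circadian clock genes, 6 were lower and 1 higher at 24 h, with a range from -3.06 to 3.68. Of 6 WRKY factors 5 were lower, of 5 listed DREB genes 4 were lower with a median of -4.07, and of 8 jasmonate response genes 3 were lower. Of 13 aquaporins 11 were higher, with a median of 1.00, and of 10 iron deficiency genes 7 were higher, with a median of 0.55. Among these the camera call held with an estimated correlation for the clock list, at adjusted p = 0.0215, while it was lost for the others, at adjusted p = 0.0831 for WRKY factors, 0.226 for the DREB list, 0.226 for aquaporins, 0.354 for the jasmonate response and 0.354 for iron deficiency. The leaf marker list, at a median of -0.40, passed at an adjusted p of 0.0373 within the planned lists. It did not pass when planned and added lists were adjusted together, at 0.0570, or with an estimated correlation, at adjusted p = 0.534. Its call within the planned lists was lost without mock replicate 2 of 6 h and mock replicates 1 and 2 of 24 h in turn, at 0.447, 0.146 and 0.0955 and medians of 0.09, -0.05 and -0.25. The median was -0.86 and -0.72 without mock replicates 1 and 3 of 6 h and -1.01 without mock replicate 3 of 24 h. By limma 3338 genes changed relative to that difference, 1539 higher and 1799 lower, against 3385 by edgeR and 7943 with the values as deposited, of which 6867 were higher and 1076 lower.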

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

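The tests on the mock time course and on single libraries, and the count of splits that part the same-numbered pairs of 6 h, were chosen after the results had been seen; the splits of the samples were planned before. The treatment effect differed between the times for 106 genes by an interaction test. Of 100 splits of the libraries within each time, drawn with the real one, 1 gave as many calls as the real 106, the real split itself, and the highest of the others gave 69, so chance can be excluded at 0.05 for this count. Of the 37 drawn splits that, like the real one, part the 3 same-numbered pairs of 6 h, 1 gave as many, the real one, and the highest other gave 49; the pairs follow the numbers of the titles. Of the printed genes, the interaction was past the threshold for Os02g0541500, at a log2 difference of -2.90 ± 0.54 (SE) with a limma adjusted p of 0.0237, and for Os07g0631200, at 2.26 ± 0.36 (SE) with a limma adjusted p of 0.0104. The former was lost in 7 of 12 refits without 1 library, at differences from -3.01 to -2.71, and with a replicate block within each time by the source-name numbers, at an adjusted p of 0.127, and its difference was -1.68 with a pseudocount of 8.

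The count of 10 genes for the mean of both times was reached by 3 of 100 splits, the real one included. Of the 37 drawn splits that part the 3 pairs of 6 h, 2 gave as many, a share of 0.0541, so chance is not excluded for it. The highest other split gave 106, because it exchanges the groups at 24 h and so counts the genes whose effect differed between the times. For each of the other results 10 splits exist, too few for a share under 0.05. The real 319 genes at 6 h stood against at most 0 in another split, with 1 split as large, the real 22 at 24 h against at most 0, and the real 7943 of the time course against at most 0. The real 5 lists at 6 h stood against a highest other of 6, with 3 of 10 splits giving as many; the splits that, like the real one, part the 3 same-numbered pairs gave at most 2, and those with 6 keep pair 1 together. The real 3 lists at 24 h stood against a highest other of 7, with 7 of 10 giving as many.

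Effects at 6 h ran along the change of mock roots between 6 h and 24 h, with a covariance across genes of 0.165 and r = 0.62. Both quantities use the same 6 h mock libraries, but unchanged groups simulated on those controls with the observed correlation between genes gave a mean covariance of 0.036 and a middle 95% that ended at 0.0988, which argues against the shared controls as the whole source. Refits argue against a single mock library of 24 h, with 0.166 against a bound of 0.126 in the nearest, while a single library of 6 h stays open, since without mock replicate 3 the covariance of 0.148 lay within the error of its simulated bound of 0.143, which is 0.132 to 0.154. A harvest at another hour of day would move the clock genes, yet their root mean square log2 fold change of 0.16 at 6 h, against 2.02 between the times, lay at percentile 14.6 of 10000 random lists of matched level. An effect of piperonylic acid on the timing of root expression may account for the pattern, and it was not tested. Noise in the 6 h libraries, the shared controls among them, may do so as well. So may any handling that the 3 mock libraries of 6 h shared, which was not tested because the labels give no batch.

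Diterpenoid phytoalexin, phenylpropanoid entry and monolignol genes were lower at 24 h by camera, at adjusted p = 0.645 for each with an estimated correlation; PR, jasmonate and WRKY lists did not pass. The pattern may rest on single libraries: the median of the diterpenoid phytoalexin list went from -0.46 to 0.29 without mock replicate 2, whose score was 1.77, and to 0.06 without treated replicate 3, whose score was -1.48. The greater depth of mock replicate 1 is argued against, since without that library the median was -1.001. Whether either library differed in plants, handling or library preparation stays open, and no biological explanation was tested.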

How the results depend on the processing

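The replicate blocks within each time and the values moved by the median shift were chosen after seeing the data. Leaving out 1 library at a time gave 4 to 741 genes at 6 h, 3 to 30 at 24 h, 0 to 246 for the mean of both times and 38 to 471 for the difference between the times, against 319, 22, 10 and 106. No gene of the difference calls changed sign. The calls of 6 h and 24 h could not change sign, since in all of them the treated libraries were separated from the mock libraries. The lists numbered 3 to 6 at 6 h and 0 to 7 at 24 h, against 5 and 3. Sample quality weights gave 686, 40, 30 and 239 genes and 0 lists at 24 h, DESeq2 gave 679, 53, 153 and 342 genes, and the replicate block within each time gave 802 genes at 6 h, 202 for the mean, 376 for the difference and 5 lists at 24 h. By the numbers in the source names this block gave 65, 0, 0 and 25 genes, 2 lists at 6 h and 7 at 24 h; it leaves 1 mock library of each time without a partner. With only the 6 libraries of 6 h the count there was 152. The mean of both times gave 3 genes with a pseudocount of 0.5, 2 with a minimum mean of 50, 22 with quantile normalisation, 30 with a replicate block and 3 with edgeR. The 24 h lists numbered 1 with no filter, 1 with a minimum mean of 50 and 5 with quantile normalisation. With an estimated correlation 0 planned lists passed at 6 h and 0 at 24 h, with 0 and 0 at an unadjusted p under 0.05; with fry 0 and 0 passed, with 1 and 0 unadjusted. The 24 h median of the diterpenoid phytoalexin list reversed to 0.024 with sample quality weights, 0.291 without mock replicate 2 and 0.056 without treated replicate 3 of 24 h, and the left-out range reached -1.001. The mock time course gave 3321 genes with TMM, 3503 with quantile normalisation, 3385 with edgeR, 3253 with DESeq2 and 3338 with the median shift removed, against 7943; these alternatives rescale the times together. For the other changes the cause was not tested. Depth limits calls for genes with few reads, and the removal of a library also lowers the number of samples.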

Other observations

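The plastidial isoprenoid list, which supplies the precursors of diterpenoids, had 8 of 9 genes positive at 6 h, with a median log2 fold change of 0.42, and 8 of 9 negative at 24 h, with a median of -0.32. It did not pass at either time, and its score was 1.08 in replicate 2 of the 24 h mock group. The tau glutathione S-transferase cluster, detoxification enzymes, had 12 of 14 positive at 6 h with a median of 0.20 and 8 of 14 positive at 24 h with a median of 0.03, and did not pass at either time.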
